A study of Mus musculus with 2 samples.

How the data were processed

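The arrays measured RNA in the skin of newborn mice of the strain C57BL/6N, on postnatal day 0, with and without the gene Pla2g4e. There were 2 arrays, 1 per genotype, and the RNA on each came from equal parts of the skin RNA of 5 animals, per the labels. Total RNA was purified on RNeasy Mini columns, and 200 ng of it was amplified and labelled with Cy3 using the Low Input Quick Amp kit, per the labels' protocols. Each pool was hybridised to 1 array of an Agilent 1-colour design, number 026655, whose probes are 60 bases long and carry positions on the mouse assembly mm9, per the file headers. Both arrays lay on the same slide, in different positions, so that position on the slide and genotype cannot be told apart.

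Spots were read with Agilent Feature Extraction 11.5.1.1 under the protocol GE1_1105_Oct12, per the submitters' processing notes and the file headers. The deposited scanner files give the intensity of each spot on a linear scale, from which the software had already subtracted the background and removed spatial trends, per the file headers. The files also give an error for each spot from the software's own error model, and marks for spots that are well above background, saturated, non-uniform or unlike their replicates. The deposited value table holds a ratio for each spot, on a linear scale and not centred by gene. Set against the scanner files, it equalled the processed intensity divided by a constant for each array, 2406 for the wild-type pool and 2273 for the knockout pool, over all 44397 spots. Its medians were 0.0946 and 0.0969. Each array had 43020 spots outside the controls, and 0 per-sample columns of unknown origin were met.

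The values used here were log2 of the processed intensity, averaged over the spots of a probe, minus the 75th percentile of the same quantity over the probes of that array. Control spots were left out, as were 234 outlier spots, which removed 7 probes, while saturated spots would have been kept but numbered 0. Of 39429 probes, 28583 were named through their accession, 2204 through their symbol and 162 through a synonym, in a RefSeq table of the assembly GRCm38.p6 that served for names alone. A further 1358 kept the name in the file, and 7122 had no gene name. These probes stood for 23970 genes. A gene was represented by its brightest probe among those well above background on both arrays, and 19210 genes had such a probe. Of the 5233 genes with more than 1 measured probe, 1413 had probes that differed in sign; among such genes with a difference of at least 2-fold there were 10 of 108.

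With 1 array per group there was no replicate error among pools or animals, no test was run and no p-value is given. A difference is the log2 value of the knockout pool minus that of the wild-type pool, and genes were counted at a fixed size of 2-fold. Error within the arrays was taken from the software's error model, with a median of 0.20 log2 for a difference, and from 334 probes printed 10 times, whose spots gave a median SD of 0.037 log2 for the difference. Both describe spots and leave out the animals. Where a gene was well above background on 1 array alone, its fold is a lower bound, the bright value over the higher of the dim value and the lowest signal among probes well above background on the dim array.

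In all, 27 gene lists of pathways, cell types and neighbouring genes were drawn up. They covered N-acylethanolamine metabolism, other phospholipases A2, eicosanoids, terminal differentiation, psoriasis-associated genes, basal keratinocytes, hair follicle, barrier lipids, cholesterol synthesis, interferon response, cell cycle, immediate early genes, the circadian clock, sex-linked genes and the neighbours of Pla2g4e. The other lists were markers of skeletal muscle, white and brown adipocytes, fibroblasts, endothelium, macrophages and dendritic cells, neutrophils, T cells, mast cells, erythroid cells, melanocytes and Schwann cells. For a list with at least 5 measured genes, its value is the median difference of its members minus the median of all measured genes. That value was placed among 10000 random lists of the same size, drawn to match the members in 20 bins of mean signal, as a description of these arrays. Members were counted at 1.5-fold. The lists, the sizes, the alternatives and the rule for naming genes were fixed before the data were examined, except for 1 older alias, that of Cstdc5, which was added later.

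The genes named were Pla2g4e; the 12 largest differences in each direction among genes of at least 2-fold, with a signal above the median of measured genes and all measured probes of 1 sign; the 5 largest bounds in each direction; and up to 4 members per list, the 2 highest and the 2 lowest. Members needed to spell out a count of 5 or fewer were named too. Other genes are said to have been picked after their values were seen. A few genes that the rule takes are not reported here.

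Alternatives covered the scaling (the 75th percentile over probes above background, the median, quantile normalization, cyclic loess), the background (normexp with an offset of 50), the deposited value table, the mean over probes, outlier spots kept, the filter on dim probes, the fold size, the mean of list members, unmatched random lists and another mark of detection. A correction for probe GC content in 10 bins, and counts without genes on X and Y, were added after the data had been seen. The steps were tested on simulated data for the comparison of knockout with wild type over 19210 genes with a noise SD of 0.1 log2. All 100 genes changed by 2 log2 and all 100 changed by 1.3 were called, with 0% of the unchanged genes. That noise was below the median scanner error of 0.20 log2 and held no differences among animals. These calls therefore check the steps and give no rate of false calls in the data. Of 200 random lists of 20 genes, 5.5% lay outside the central 95%, and of 50 lists shifted by 0.3 log2, 100% did. Calculations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.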

Results

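Skin RNA from newborn mice without Pla2g4e was compared with skin RNA from wild-type mice on 2 arrays, each holding a pool from 5 animals. Pla2g4e encodes a cytosolic phospholipase A2 that makes the precursors of N-acylethanolamines, and the series asks how its loss bears on psoriasis-like inflammation of the skin. The median spot signal was 249 in the wild-type pool and 241 in the knockout pool. Of the probes, 78.0% were well above background in the wild-type pool and 80.8% in the knockout pool. With 1 array per group the differences have no replicate check, and the number of arrays limits their precision. The scanner software gave a difference a median error of 0.20 log2, and 0.30 at the 95th percentile of genes.

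Pla2g4e RNA was lower in the knockout pool but still detected. Its probe, A_52_P203948 for NM_177845 at mm9 chromosome 2, 119992643 to 119992702, read 662 in the wild-type pool and 320 in the knockout pool. These readings are unscaled. After scaling, the difference was -0.96 log2 with a scanner error of 0.20, which left 51.4% of the wild-type level. A second probe, A_55_P2122896 for XM_006499774 at 120071162 to 120071221, read 10.6 and 11.8, near background, and was well above background in the knockout pool alone. The part of the gene that was deleted is not given in the sources used here. A probe outside it checks nothing about the labels, and whether either probe lies in an exon that was removed is unknown.

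The gene with the largest difference near Pla2g4e was its neighbour Pla2g4d, a phospholipase of the same family. Pla2g4d, with a probe at mm9 chromosome 2, 120091617 to 120091676, was 6.42-fold higher in the knockout pool after scaling, with unscaled readings of 592 against 98.3. Pla2g4f, another member of the family, was 1.53-fold higher. These were the 2 of 17 measured neighbours that were at least 1.5-fold higher, and 0 were lower; Pla2g4b differed by -0.11 log2 and Sptbn5 by -0.08. The median of the neighbours was 0.06 log2 and lay at percentile 79.3 of matched random lists, but at 98.0 among bright genes alone, and their mean at 99.2.

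Genes of N-acylethanolamine and eicosanoid metabolism showed no shift as groups. Among 20 measured genes of N-acylethanolamine metabolism and its receptors the median was 0.01 log2, at percentile 54.7 of random lists. Ppara, the nuclear receptor for fatty acids, was the 1 member at least 1.5-fold higher, at 1.21 log2, and Pla2g4e the 1 lower; Abhd4 stood at 0.57 and Mgll, the monoacylglycerol lipase, at -0.58. Of 29 other phospholipases A2, 4 were at least 1.5-fold higher, namely Pla2g4d, Pnpla7 (0.88), Pnpla2 (0.83) and Pla2g4f. Another 5 were lower, namely Pla2g4c (-1.36), Pla2g2e (-1.3), Pnpla5 (-1.15), Pla2g10 (-0.88) and Pnpla3 (-0.61), and the list's median was 0.00 at percentile 56.2. Of 26 eicosanoid genes, the receptors Ptgdr (1.07) and Ptgfr (0.74) were the 2 that were higher and 0 were lower. Ptger1 stood at -0.48 and Ptges2 at -0.44, and the median was 0.02 log2 at percentile 63.6.

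Across all measured genes, 433 were at least 2-fold higher in the knockout pool and 277 at least 2-fold lower, together 3.70% of the 19210. The median difference was 0.01 log2 and the central 95% ran from -0.76 to 0.95. The signals of the pools had a correlation of 0.99 across genes, which are not independent replicates. Among genes with a signal above the median and all probes of 1 sign, the 12 largest differences toward the knockout included Krt6b, a keratin of stressed epidermis (8.46-fold), the calcium-binding proteins S100a9 (5.14-fold) and S100a8 (4.02-fold), the cornified envelope gene Sprr2d (4.51-fold) and the acute phase gene Saa1 (4.43-fold). They also held Ankrd2, a muscle ankyrin repeat protein (9.87-fold), Gm5478 (9.62-fold), the transcription factor Zbtb16 (7.76-fold), Galnt15 (5.56-fold), Hif3a (5.45-fold) and Fkbp5, a co-chaperone of steroid receptors (4.08-fold). Gm5478 and Krt6b lie close together on chromosome 15, and a probe for 1 near-identical paralog can bind RNA of another. Under normexp background correction the counts were 235 and 123; that correction draws low signals together.

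**Figure D1:**
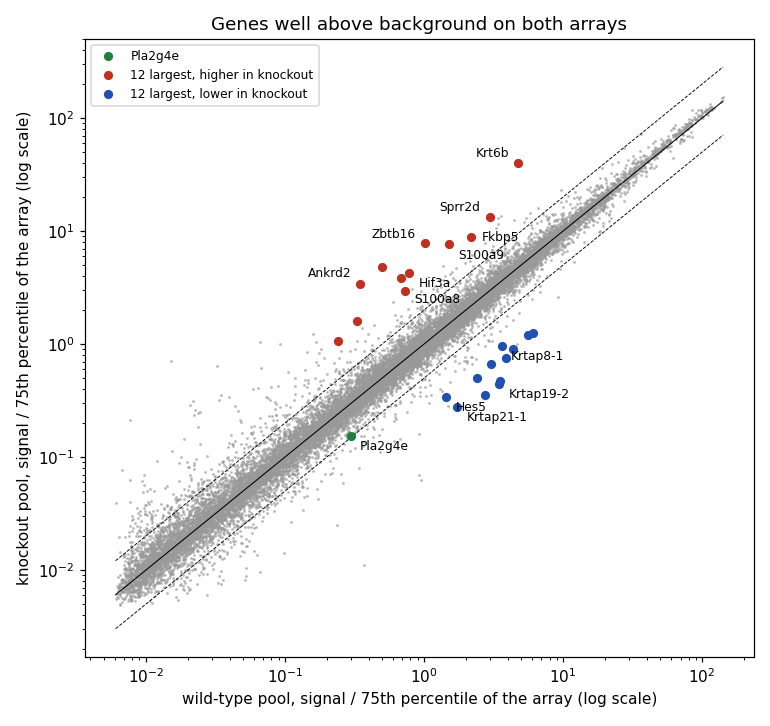
Signal of each gene over its array's 75th percentile in the wild-type pool (x axis, log scale) and the knockout pool (y axis, log scale), 1 array each; the solid line marks equal signal, the dashed lines 2-fold, and coloured points are Pla2g4e and the 12 largest differences each way among genes with a signal above the median and probes of 1 sign. Krt6b lies highest among the named genes at 40.3 in the knockout pool against 4.77, and Pla2g4e lies just inside the lower dashed line.

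Within the same brighter genes, the 12 largest differences toward the wild type came almost wholly from a region of chromosome 16 that holds genes of the hair shaft. Of the 12, 11 with probes on mm9 chromosome 16 lay between 3.79-fold and 7.93-fold lower in the knockout pool. Of these, 5 were named as keratin-associated proteins, the matrix proteins that embed hair keratins: Krtap19-2 (-2.99 log2), Krtap16-3 (-2.95), Krtap21-1 (-2.64), Krtap22-2 (-2.37) and Krtap8-1 (-1.92). The others in the region were Gm41515 (-2.89), 1110025L11Rik (-2.29), Gm35091 (-2.27), Gm10228 (-2.27), Gm6358 (-2.21) and Gm10229 (-2.19). The 1 gene elsewhere was Hes5, a Notch target, at -2.08. Over all genes with a Krtap name, a family picked after its values were seen, 41 of 51 measured genes were at least 2-fold lower and 0 at least 2-fold higher. Of the 51, 3 lay above 0, up to 0.75, and relatives under other names were not counted. Its median was -1.51 log2, and its lowest member was Krtap19-3 at -5.07. Sequence shared among Krtap paralogs can spread signal across their probes.

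Hair follicle genes outside the Krtap family were lower as a group. Of 33 measured members, 23 were at least 1.5-fold lower in the knockout pool, and the median was -0.83 log2, with all 10000 random lists above it. The hair keratins Krt34 (-1.50) and Krt87 (-1.49) were lowest, Edar, a receptor of follicle formation, stood at 0.14, and Krt84, a hair keratin with a dim probe, was the 1 higher member at 2.34. Melanocyte genes were lower beside them: Mlana (-0.66) and Oca2 (-0.62) were the 2 of 10 at least 1.5-fold lower, Tyrp1 stood at -0.03 and Gpr143 at 0.35. The melanocyte median was -0.32 log2, with 8 of 10000 random lists as low.

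**Figure D2:**
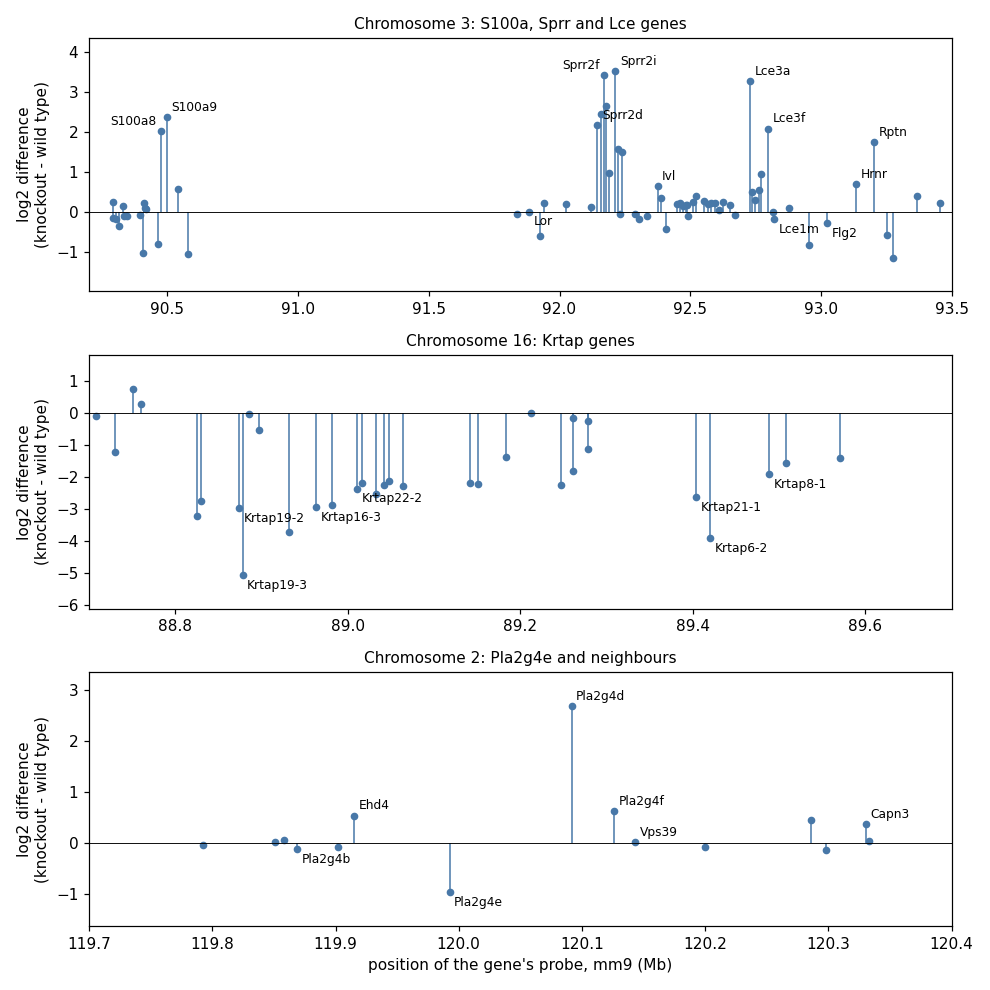
Log2 difference, knockout pool minus wild-type pool, of each measured gene (points) at the mm9 position of its probe (x axis, Mb), for the S100a, Sprr and Lce genes on chromosome 3, the Krtap genes on chromosome 16 and the neighbours of Pla2g4e on chromosome 2. Sprr2 genes reach 3.51 log2 above 0, most Krtap genes lie below 0 and down to -5.07, and Pla2g4d stands at 2.68 beside Pla2g4e at -0.96.

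Psoriasis-associated and inflammatory keratinocyte genes were higher as a group, with exceptions among the cytokines and other members. Of 46 measured members, 20 were at least 1.5-fold higher in the knockout pool and 5 lower, with a median of 0.22 log2 that lay above all 10000 random lists. The size depended on the setting: the median was 0.72 among bright genes alone and 0.15 with normexp, and the mean of members was 0.65. Highest were the cornified envelope precursors Sprr2i (3.51) and Sprr2f (3.42). All 9 Sprr2 genes, a family picked after its values were seen, were above 0, with a median of 2.17, though near-identical members can share signal. The 5 lower members were the defensin Defb6 (-2.02), the chemokine Ccl2 (-0.94), Tnf (-0.87), S100a7a (-0.81) and Il23a (-0.61). Among members picked after their values were seen, Krt6a stood at 1.97, Krt16 at 0.94, Slpi at 2.55 and Lcn2 at 1.79. Il17a (-0.01), Il17f (0.01) and Il22 (-0.14) had dim probes.

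Neutrophil markers were higher beside these genes, and S100a8 and S100a9 are abundant in neutrophils as well as in inflamed keratinocytes. Of 14 measured neutrophil markers, 9 were at least 1.5-fold higher, and the median of 1.08 log2 lay above all 10000 random lists. The collagenase Mmp8 (2.56) and the chemokine receptor Cxcr2 (1.92) were highest, both from dim probes, while Csf3r stood at -0.04 and Camp, the 1 lower member, at -1.0. With normexp background correction, which damps low signals, the median was 0.61 log2. Among bright genes alone, fewer than 5 of the 14 markers remained, so the list had no median there and rests mostly on dimmer probes.

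Terminal differentiation genes were slightly higher as a group. Of 45 measured members, 6 were at least 1.5-fold higher in the knockout pool, led by Lce3a (3.26) and Lce3f (2.08). The median of 0.19 log2 lay above all 10000 random lists, and it was 0.13 with quantile normalization and 0.14 with normexp. Lce1 genes, many of them in this list, also had a median of 0.19. Paralogs that share signal are not independent, as the random lists take members to be. Krt77, a suprabasal keratin, was the 1 lower member at -1.0, and the transcription factor Ovol1 stood at -0.43. Of members picked after their values were seen, Lor stood at 0.00, Krt1 at 0.11 and Krt10 at 0.14. Basal keratinocyte and basement membrane genes had a median of 0.16 log2 over 15 genes, at percentile 98.9. Dst, a hemidesmosome protein (0.72), was the 1 member at least 1.5-fold higher and 0 were lower; Lamb3 stood at 0.48, Krt5 at -0.05 and Bcam at -0.15. The basal list fell within the central 95% of random lists when probes of a gene were averaged, at percentile 85.2.

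Cholesterol synthesis genes were lower as a group, and barrier lipid genes were not. Of 23 cholesterol synthesis genes, 5 were at least 1.5-fold lower in the knockout pool and 0 higher: Idi1 (-1.0), Fdps (-0.83), Cyp51 (-0.74), Nsdhl (-0.64) and Lss (-0.59). Their list's median was -0.44 log2, below all 10000 random lists, with Tm7sf2 (0.47) and Ebp (0.27) highest. Of 30 barrier lipid genes, 5 were lower, namely Fa2h, the fatty acid 2-hydroxylase (-1.67), Elovl3 (-1.13), Cers4 (-0.81), Fasn (-0.81) and Scd1 (-0.68). Degs2, a sphingolipid hydroxylase, was the 1 higher at 0.98, followed by Sptlc3 at 0.44. The barrier median was 0.09 log2 at percentile 94.1 (99.8 among bright genes alone), and the mean of the same members had the other sign, -0.07.

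Interferon-response genes were higher and cell cycle genes lower. Of 30 interferon-response genes, 13 were at least 1.5-fold higher and 0 lower, and the median of 0.54 log2 lay above all 10000 random lists. The antiviral genes Ifi44 (1.17) and Rsad2 (0.99) were highest, and Irf7 (-0.57) and Cxcl10 (-0.14) lowest. All 27 cell cycle genes were below 0, with a median of -0.37 log2, under all 10000 random lists. The 3 at least 1.5-fold lower were the replication licensing genes Mcm2 (-0.95), Mcm5 (-0.79) and Mcm3 (-0.64), and 0 were higher; Ccnb2 stood at -0.08 and Cenpe at -0.07.

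Immediate early and clock genes held single large differences, with medians inside the central 95% of random lists. Fos (0.93), Hmox1 (0.74), Atf3 (0.69) and Klf6 (0.69) were the 4 of 22 immediate early and stress genes that were at least 1.5-fold higher. Lower by that size were 0; Nr4a1 stood at -0.45 and Egr3 at -0.54, and the median was 0.11 log2 at percentile 94.8, or 99.6 among bright genes alone. Of 17 clock genes, 5 were higher, namely Per1 (1.91), Ciart (1.1), Nr1d1 (0.94), Nfil3 (0.71) and Per2 (0.62). Per3 was the 1 lower at -0.66, Dbp stood at -0.38, and the median was 0.15 log2 at percentile 97.0, with the mean at 97.9.

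**Figure D3:**
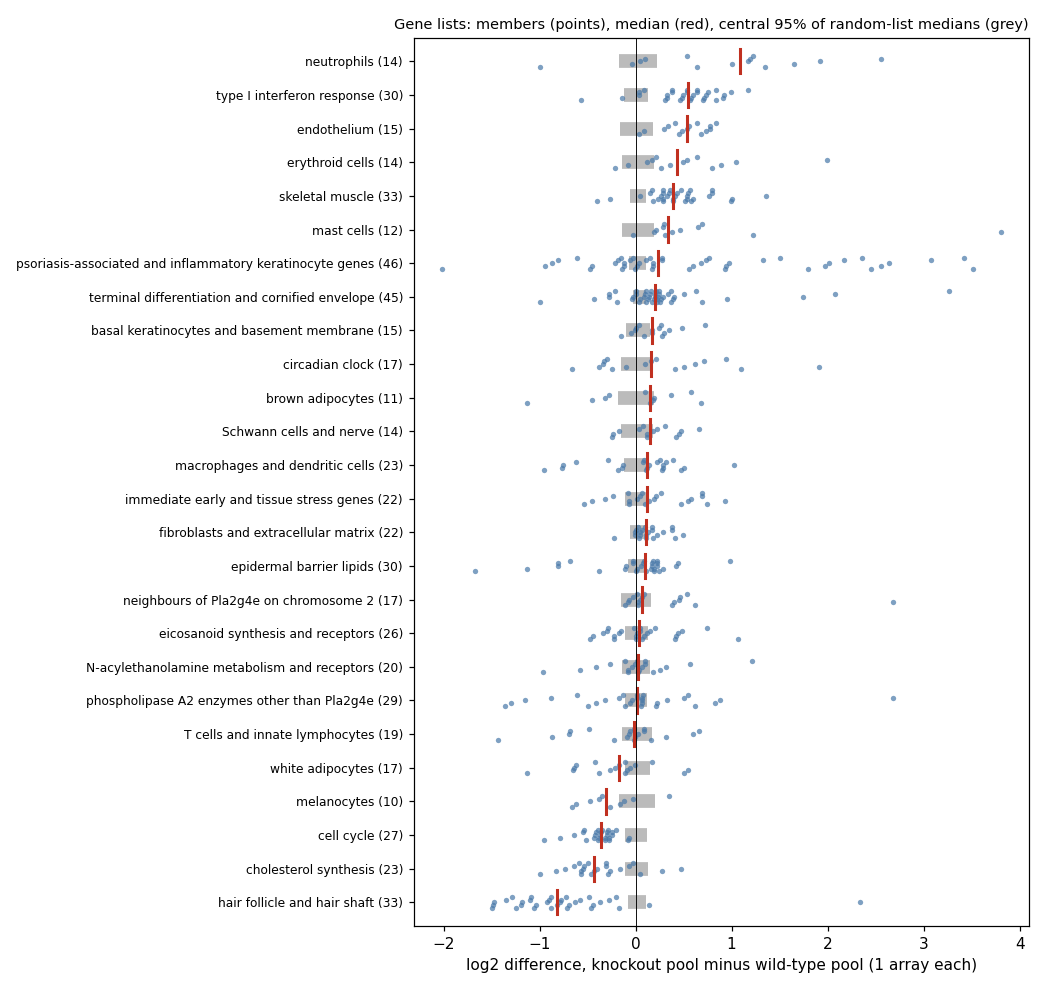
Log2 difference, knockout pool minus wild-type pool (x axis), of the measured members of 26 gene lists (points, number in brackets), with the list median (red) and the central 95% of random-list medians (grey), drawn on the scale of the differences. Neutrophil markers lie farthest to the right and hair follicle genes farthest to the left.

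Markers of several tissues that whole skin can include were higher in the knockout pool. The median of 33 skeletal muscle genes was 0.38 log2, above all 10000 random lists; 7 were at least 1.5-fold higher, led by the slow troponin Tnni1 (1.36) and Pvalb (1.0), and 0 were lower, with Myh2 at -0.40 and Mb at -0.27. Endothelial genes had a median of 0.52 over 15 genes, all above 0 and above all 10000 random lists, with 6 at least 1.5-fold higher and 0 lower. Emcn (0.84) and Tie1 (0.77) were highest, and Flt4 (0.09) and Kdr (0.03) lowest. Erythroid genes had a median of 0.42 over 14 genes, with 2 of 10000 random lists as high. The 5 at least 1.5-fold higher were the embryonic globin Hbb-y (1.99), Rhd (1.04), Rhag (0.89), Ahsp (0.80) and Hbb-b1 (0.64), and 0 were lower; Hbb-bh1 stood at -0.08 and Car1 at -0.21. Mast cell genes had a median of 0.33 over 12 genes, with 8 of 10000 random lists as high. Fcer1a (3.80, from a dim probe), Hdc (1.22), Mrgprb1 (0.69) and Cpa3 (0.65) were the 4 higher and 0 were lower; Ms4a2 stood at 0.19 and Mrgprb2 at -0.03.

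White adipocyte genes were lower, while brown adipocyte, fibroblast and Schwann cell genes had medians within the central 95% of random lists. Plin1, the lipid droplet protein (-1.13), Agpat2 (-0.65), Adipoq (-0.64) and Retn (-0.62) were the 4 of 17 white adipocyte genes at least 1.5-fold lower. Higher by that size were 0; Thrsp stood at 0.55 and Plin4 at 0.50, and the median was -0.18 log2, with 32 of 10000 random lists as low. Brown adipocyte genes had a median of 0.14 over 11 genes at percentile 93.0 and a mean of -0.02, with Ppargc1a (0.68) the 1 higher, Elovl3 the 1 lower at -1.13, Ucp1 at 0.58 and Cidea at -0.45. Fibroblast genes had a median of 0.10 over 22 genes at percentile 92.2, with 0 members past 1.5-fold; Pdgfra stood at 0.49, Mfap5 at 0.41, Dpt at -0.01 and Lum at -0.23. Schwann cell genes had a median of 0.14 over 14 genes at percentile 94.3, with Cdh19 (0.66) the 1 higher, 0 lower, Foxd3 at 0.47, Egr2 at -0.24 and Sox10 at -0.25.

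Among other immune cells, 4 genes of antigen presentation were lower, and the median of the list that holds them was not. Macrophage and dendritic cell genes had a median of 0.11 over 23 genes at percentile 96.5, or 97.7 with normexp and 98.6 after GC correction, and a mean of 0. The 4 at least 1.5-fold lower were the MHC class II genes H2-Ab1 (-0.95), H2-Eb1 (-0.77) and H2-Aa (-0.76) and their chaperone Cd74 (-0.62), and the macrophage scavenger receptor Cd163 was the 1 higher at 1.02, followed by Mrc1 at 0.50. T cell and innate lymphocyte genes had a median of -0.03 over 19 genes at percentile 32.7. The 4 lower were Klrb1c (-1.43), Cd3g (-0.87), Xcl1 (-0.69) and Cd3d (-0.68), and 2 were higher, among them Il7r (0.66). Of the 26 lists with a median, 9 lay above the central 95% of random lists, 5 below and 12 within, where 1.3 outside would be due to chance if genes of a list were independent.

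Genes well above background in 1 pool alone numbered 811 for the knockout pool and 186 for the wild-type pool. More probes passed this mark on the knockout array, 80.8% against 78.0%. Near-equal signals can pass it on 1 array alone, as the second Pla2g4e probe did at 10.6 and 11.8. The unequal counts therefore do not measure how many genes were switched on or off. As a bound, 167 and 123 of these genes differed by at least 2-fold. Toward the wild type the 5 largest were Eif2s3y (at least 512-fold lower in the knockout pool), Ddx3y (at least 276-fold), Sly (at least 27.3-fold), Gm20736 (at least 19.3-fold) and Gm21996 (at least 18.1-fold), all with probes on the Y chromosome or its unplaced parts. Kdm5d and Uty, also Y-linked, were well above background in the wild-type pool alone, and Xist, the RNA of the inactive X, was 3.87-fold higher in the knockout pool. In unscaled signal, Ddx3y read 2893 in the wild-type pool and 2.37 in the knockout pool, and Eif2s3y read 5363 and 6.35. The knockout pool therefore held no male RNA that these Y-linked genes could detect, while the wild-type pool did. The pools were not balanced for sex, and every difference given here also compares pools of unlike sex. Toward the knockout the 5 largest were Gm9758 (at least 19.6-fold higher), Speer4d (at least 17.1-fold), the olfactory receptor Olfr352 (at least 11.3-fold), the chitinase Chia1 (at least 10.6-fold) and 2010106E10Rik (at least 8.99-fold). Sex-linked genes had 1 member measured on both arrays and no list median.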

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

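Probes without a gene name lay outside every comparison above, and they were examined only after the other results had been seen. Of 4691 such probes measured on both arrays, 80 were at least 2-fold higher in the knockout pool and 75 at least 2-fold lower. They drew attention because they lie in data not used elsewhere. Their counts are no excess over the named genes, of which 3.70% differed by that size. The lowest, A_55_P2007103 at mm9 chromosome 16, 88924295 to 88924352, stood at -4.80 log2 near Krtap19-9b, which was lower too. Of these probes, 14 lay within 10000 bp of a named gene with a difference of at least 2-fold in the same direction. How many would do so by position alone was not counted.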

How the results depend on the processing

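The correction for GC content and the counts without X and Y were chosen after seeing the data. No named gene reversed its direction, and no list outside the central 95% of random lists moved to the opposite side of it. Some list values inside the central 95% did change sign, as for barrier lipids by the mean of members. Pla2g4e stayed between -0.81 and -0.99 log2, and the named genes moved in 3 of 192 alternatives, all 3 from averaging probes, among them Hif3a 1.66 and 1110025L11Rik -2.61. Among 337 alternatives of list medians, 28 moved and 10 crossed the edge of the central 95%; basal keratinocytes fell inside it in 3, at percentiles 85.2 (averaged probes), 96.7 (mean of members) and 96.5 (unmatched lists). The other 7 rose above it: barrier lipids 99.8, immediate early genes 99.6 and neighbours 98.0 among bright genes, the clock 97.9 and neighbours 99.2 by the mean, and macrophages 97.7 with normexp and 98.6 after GC correction. Counts of genes higher and lower were 235 and 123 with normexp (234 and 123 of them shared with the first count), 940 and 558 with no filter on dim probes, 100 and 80 for bright genes, 1297 and 857 at 1.5-fold, and 141 and 64 at 3-fold; the last 4 follow from the number of genes kept or the size asked. Genes detected in the knockout pool alone numbered 270 at 1.5-fold. Without X and Y the counts were 420 and 271. With normexp the medians were 0.14 for differentiation, 0.15 for psoriasis genes, 0.03 for barrier lipids, 0.45 for interferon and 0.61 for neutrophils. Quantile normalization gave differentiation 0.13. Averaging probes gave psoriasis genes 0.26, basal keratinocytes 0.08 and cholesterol -0.37, and no filter gave neutrophils 1.18. Bright genes gave psoriasis genes 0.72, barrier lipids 0.17, cholesterol -0.37, immediate early genes 0.20, white adipocytes -0.25 and neighbours 0.22. The mean of members in place of the median gave differentiation 0.26, psoriasis genes 0.65, hair -0.77, barrier lipids -0.07, interferon 0.48, white adipocytes -0.25, brown adipocytes -0.02, macrophages 0, neutrophils 0.85, T cells -0.17, mast cells 0.68 and neighbours 0.29. The cause of these shifts was not tested. Signal little above background limits single values such as those of Mmp8, Cxcr2 and Fcer1a. No paired analysis was possible because each group has 1 array, which also rules out leaving out a replicate.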

Other observations

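The lists of hormone targets, the hair keratin subsets and the tests in this part were chosen after the main differences had been seen, except the loess scaling, which was planned; for the follicle stages the values had been seen before the test and its bounds were set, and for sex chromosome dosage the test was widened after its first value. Known targets of the glucocorticoid receptor were higher in the knockout pool. Of 34 measured, 19 were at least 1.5-fold higher and 0 lower, with a median of 0.90 log2, which includes 9 genes whose values had prompted the list. Besides Zbtb16, Fkbp5 and Hif3a they included Tsc22d3 (3.89-fold), a glucocorticoid-induced leucine zipper protein, Per1 (3.76-fold), Cebpd (3.40-fold) and Klf9 (3.12-fold). The targets that were not 1.5-fold higher all lay within 1.5-fold, and of these Rgcc (-0.02) and Rasd1 (-0.31) lay below 0. FOXO targets, genes switched on when insulin signalling is low, had a median of 0.78 over 23 genes, 2 of them seen beforehand. At least 1.5-fold higher were 14 of them and 0 were lower, with Depp1 (1.90), Trp53inp1 (1.86), Pik3ip1 (1.55) and Klf15 (1.36) among the higher. Skeletal muscle markers were higher too, with a median of 0.38 log2, and whether muscle in the samples adds to the FOXO median was not tested. Targets of PPAR-alpha that fasting induces had a median of 0.16 over 25 genes, 2 of them seen beforehand, with 4 at least 1.5-fold higher, among them Pdk4 (1.46), Ppara (1.21) and Plin5 (1.20), and 0 lower.

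Within the hair follicle, keratins of the inner root sheath had a median of -0.72 log2 over 7 genes, and keratins of the hair shaft a median of -1.23 over 12 genes, of which 11 were at least 1.5-fold lower and Krt84 was the 1 higher. Lce1 genes had a median of 0.19 over 14 genes and Lce3 genes a median of 0.75 over 6. These are differences of the arrays, with the median of each family open to shared signal between paralogs.

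The hormone pattern is a hypothesis found on these data. Over targets whose values had not been seen, the median was 0.57 log2 for 25 glucocorticoid targets and 0.70 for 21 FOXO targets. Both lay above all 10000 random lists, and the 18 of those FOXO targets outside the glucocorticoid list had a median of 0.62. For 23 unseen PPAR-alpha targets it was 0.15, at percentile 99.3, a small shift. The unseen targets were measured on the same arrays that gave the hypothesis, and the random lists take genes to be independent. Targets of a shared regulator can move together, so these medians are no independent test of the hypothesis. Higher glucocorticoid signalling, lower insulin signalling or both in the knockout pool may account for part of the differences. This could arise through genotype, feeding, time after birth or handling, and the design has no value that separates these. The glucocorticoid and FOXO lists share 3 genes. A FOXO target outside the glucocorticoid list may still respond to glucocorticoids, so the value of 0.62 does not show a separate FOXO signal. Sex differed between the pools as well.

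The sex of the animals is the second pattern. If dosage of the sex chromosomes were the main cause, genes on X and Y should make up much of the genes at least 2-fold different. Among genes measured on both arrays they made up 2.68% (19 of 710), against 3.65% of all measured genes; both shares leave out Y-linked genes detected in the wild-type pool alone. With genes detected in 1 pool included, 40 of 1000 genes, or 4%, lay on X or Y. Location there does not make dosage the cause of a difference, so 4% is the most that dosage of the sex chromosomes could cover through genes on them. Sex acting on other chromosomes cannot be told apart from genotype: Xist in the wild-type pool was 25.9% of its level in the knockout pool, and no arrays compare the genotypes within 1 sex.

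The lower hair shaft genes are the third pattern. A trend with signal or probe GC content is argued against by the list median of -0.82 after loess or GC correction, the one nearer to 0, and a local defect of an array by the median of -0.001 log2 over 1802 spots around the probes. Fewer follicles of every stage would lower keratins of the inner root sheath and the shaft alike. Their medians lay 0.50 log2 apart, between the bounds set for this test, of which the upper was the 0.77 of both interquartile ranges together. Both keratin sets belong to follicles that already form hair. Their gap therefore cannot separate fewer follicles of every stage from fewer advanced ones, and fewer follicles of every stage stay open. Fewer follicles of the most advanced stage, which may follow from a slight difference in developmental age, signal shared among paralogs and an effect of the genotype stay open too.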
